A study of Homo sapiens with 9 samples.

How the data were processed

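TRIBE-seq libraries were made from total RNA of 293T cells sorted for a fluorescent marker 24 h after transfection, then depleted of ribosomal RNA and sequenced as paired 100 bp reads, per the labels' protocols. The 9 samples fall into 5 groups: GPATCH8-ADAR (2, run 1), its non-targeting control (2, run 1), ADAR-SUGP1 (2, run 2), its control (2, run 2) and untransfected cells (1, run 2). Trimmomatic and STAR and the hg19 build are named in the submitters' processing notes. The site caller, its thresholds, the versions of these tools, the gene annotation and any use of strand are not given in the sources used here. According to the series' design text, endogenous editing events and those of the control fusion were subtracted, and events found in both replicates were kept. The labels name the second fusion as ADAR-SUGP1 in the design text and as SUGP1-ADAR in the sample descriptions; the name in the file header, ADAR-SUGP1, is used here.

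The authors deposited 1 table per fusion with whole-number counts of editing sites, not of reads, per Ensembl transcript, in columns for promoter, 5′ UTR, coding sequence, 3′ UTR, stop codon, intron and whole transcript, per the file headers. In every one of the 612 and 1340 transcript rows the whole-transcript count equals the sum of 5′ UTR, coding, 3′ UTR and intron, so promoter and stop-codon counts stand apart from it; the extent of these regions is not given. The GPATCH8-ADAR table also has 572 blank rows, which were skipped. The tables carry no positions, editing levels, read coverage or replicate values. A filter that keeps only sites called in both replicates and absent from controls leaves no control value in the tables and favours transcripts read deeply in both libraries. The labels give 1 approximate range of reads for all libraries together, so the depth of each library and of each site is unknown, and no interval based on reads was made. The labels do not say whether replicates came from separate cultures.

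Site counts were summed over the transcripts of a gene, which assumes that a site was counted for 1 transcript. Several transcripts were listed for 44 genes with GPATCH8-ADAR and 202 with ADAR-SUGP1. Gene names are those of the files: of 1513 names, 1244 were current RefSeq symbols, 123 matched 1 symbol as a synonym and 146 were not matched, by a gene table of assembly GRCh38.p14. That table was used only for names and for the background of the overlap test, since the files are on hg19, and no coordinates are given.

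Choices of tests, gene lists, named genes and alternatives were made before the data were examined, unless said otherwise. An edited gene is any gene on a fusion's list. The overlap of genes was tested with Fisher's exact test (one-sided) against 20254 genes, which are 20056 protein-coding genes of the table and 198 further listed genes. Regions were compared with Fisher's exact test over sites (over transcripts for stop codon and promoter), two-sided, with Benjamini-Hochberg adjustment over 6 regions. A permutation over genes (10000 draws) and resampling of genes (10000 draws, 95% intervals) took account of several sites in 1 gene. Sites per gene were compared with a two-sided permutation test (100000 draws). In these permutations and resamplings, genes on both lists entered each side as separate entries, without pairing, unless said otherwise. Of 20 fixed gene lists, 16 with at least 3 edited genes were compared between genes edited with 1 fusion alone. Lists such as translation factors, chromatin regulators or oxidative phosphorylation were set by patterns of gene symbols and take in a few kinases, assembly factors and other genes of like name; antisense RNAs were counted only as non-coding RNAs. Exact binomial (Clopper-Pearson) 95% intervals were given for shares. Both replicates enter each deposited count together, so p-values and intervals reflect the spread over sites or genes, not between libraries or cultures. Sites of 1 gene, and genes, are not independent replicates.

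Named genes were the 10 with the most sites per fusion, the 10 shared genes with the largest smaller count, up to 4 members of each list per fusion, all with ties in alphabetical order, and a fixed set of genes including GPATCH8, SUGP1, SF3B1, ADAR, MAP3K7 and BRD9; 1 further gene of this set is not reported here. Members of short lists beyond these (PHF5A, U2SURP, PPP2R5A, NDUFB1), genes outside the lists (TYK2, ITGB2, HAVCR2, IFNAR1, IRF3, IRAK4), and genes named under the other observations, were chosen after their values were seen. Alternatives were other backgrounds, a minimum of 2 sites per gene, genes or 1 random site per gene as the unit (100 draws), and subsets of genes. Planned tests of fusion against control, editing level, replicate agreement, overlap of positions and base context could not be run on these columns, and the part of the rule on genes holding the sites of highest editing level does not apply. Between transcripts listed for both fusions, a permutation within transcripts was set first and was replaced by an exact sign test after its result was seen.

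The functions were tested on simulated data. Fisher's test of the overlap gave p under 0.05 in 4.8% of 500 simulations with no shared genes planted and in 95.8% with 20 planted. The simulated lists were drawn evenly from all 20254 genes. They therefore do not show how the test behaves when genes differ in their chance of being called. The permutation over genes for the coding share gave it in 3.0% of 100 simulations with no difference and in 87.0% when the intronic sites of 50 of the 1675 gene entries were turned into coding sites. Fisher's test over sites gave 6.0% and 93.0%. The simulations with no difference shuffled the fusion over the gene entries, so a low rate for the permutation was fixed in advance. They do not show how either test behaves when the lists differ in depth or calling. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.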

Results

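RNA editing marks left by 2 RNA-binding proteins were mapped in 293T cells, a human embryonic kidney line that carries the SV40 large T antigen and transfects readily. GPATCH8 and SUGP1, which both carry a G-patch domain and are linked to splicing at the branchpoint by SF3B1, were each expressed as a fusion to the catalytic domain of a hyperactive Drosophila adenosine deaminase (ADAR). In this assay, TRIBE-seq, the deaminase converts adenosines near the places where its partner contacts RNA, and the inosines are read as guanosines in RNA-seq. The question was which transcripts each protein contacts. GPATCH8-ADAR was sequenced in run 1 and ADAR-SUGP1 in run 2, with 2 libraries of each fusion, 2 libraries of a non-targeting control fusion in each run, and 1 untransfected library in run 2. The deposited tables hold 1 list per fusion of sites kept in both replicates after endogenous and control editing had been removed. They therefore give a single count for each transcript of a fusion, without editing levels, read coverage or replicate values, and the read depth behind each site is unknown.

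With GPATCH8-ADAR, 797 editing sites were counted within 565 genes, and most lay in introns. NUP205, a scaffold of the nuclear pore, carried the most sites, 8 in introns of ENST00000285968.6. NDUFV3, an accessory subunit of respiratory complex I, carried 7 sites, all in the 3′ UTR of ENST00000340344.4. CCDC84 (current symbol CENATAC, a minor-spliceosome protein), the translation initiation subunit EIF3L and the chromatin remodeller HELLS carried 6 intronic sites each, and TTF2, a transcription termination factor, had 3 in its 3′ UTR and 3 in introns. There were 7 genes with 5 sites, among them the maintenance DNA methyltransferase DNMT1, ENSA, the mitochondrial DNA polymerase subunit POLG2 and the transcript CTD-2116N17.1, all with intronic sites. Most genes held few sites: 374 of the 565 had 1 site, 106 had 2, and the mean was 1.41 ± 1.02 sites per gene (SD over genes, n = 565). The 10 genes with the most sites held 7.40% of all sites. There were 32 genes with no site in the transcript body, so that 533 genes remained when at least 1 such site was required.

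ADAR-SUGP1 gave 1358 sites within 1110 genes. RPL31, a protein of the large ribosomal subunit, carried 7 sites over 5 listed transcripts, 6 of them intronic and 1 in a 3′ UTR. The mitochondrial protease gene SPG7 had 7 intronic sites, and the antisense transcript RP11-440L14.1 had 6. There were 6 genes with 5 sites. The copine CPNE1, the chromatin-remodelling subunit INO80E and the replicative helicase subunit MCM7 had theirs in introns, and NDUFS1, a core subunit of complex I, in its 3′ UTR. C7orf43 (current symbol TRAPPC14) had 4 in introns and 1 in coding sequence, and NDUFV3 had 4 in introns and 1 in a 3′ UTR. ENOSF1 had 4 intronic sites. Of the 1110 genes, 827 had 1 site and 146 had 2, with a mean of 1.22 ± 0.765 (SD over genes, n = 1110), and the 10 genes with the most sites held 3.98% of all sites. At least 1 site in the transcript body was present in 1041 genes. The files do not say whether strand was used to assign sites, so sites of antisense transcripts such as RP11-440L14.1 cannot be told from those of a gene on the other strand. Ribosomal protein genes such as RPL31 have processed copies that can share reads from exons, though 6 of its 7 sites were counted as intronic.

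Neither fusion's list held GPATCH8, SUGP1, SF3B1 or the endogenous editing enzyme ADAR. Most listed transcripts were protein-coding, 544 of 612 (88.9%) with GPATCH8-ADAR and 1216 of 1340 (90.7%) with ADAR-SUGP1. Antisense transcripts numbered 28 and 50, and long intergenic non-coding RNAs 16 and 19. Of the 9 transcript types, none differed in share between the fusions at an adjusted p under 0.05 by Fisher's exact test (two-sided, Benjamini-Hochberg over the types), the lowest unadjusted p being 0.0684 for long intergenic non-coding RNAs. Of the 612 and 1340 transcripts, 52 with GPATCH8-ADAR and 162 with ADAR-SUGP1 were listed with a count of 0 in every region, and 34 and 128 of these were protein-coding.

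Where in the transcript the sites lay differed between the fusions. Coding sequence held 17 of 797 sites with GPATCH8-ADAR (2.13%, 95% exact binomial interval 1.25 to 3.39) and 141 of 1358 with ADAR-SUGP1 (10.4%, 8.81 to 12.1). The 5′ UTR held 9 sites (1.13%, 0.518 to 2.13) and 66 sites (4.86%, 3.78 to 6.14). Introns held 630 sites with GPATCH8-ADAR (79.0%, 76.1 to 81.8) and 940 with ADAR-SUGP1 (69.2%, 66.7 to 71.7). The 3′ UTR held 141 sites (17.7%, 15.1 to 20.5) and 211 sites (15.5%, 13.7 to 17.6). The stop-codon region, which the tables count apart from the transcript total, had a site in 20 of 612 transcripts (3.27%) with GPATCH8-ADAR and in 146 of 1340 (10.9%) with ADAR-SUGP1. Of these transcripts, 11 with GPATCH8-ADAR and 87 with ADAR-SUGP1 had no site in the transcript body. Whether their stop-codon sites were also counted for another transcript cannot be told without positions. Among genes named here, CUL7, a cullin scaffold of ubiquitin ligases, carried 2 coding sites with GPATCH8-ADAR, and the cullin CUL9 and the histone deacetylase HDAC10 carried 2 coding sites each with ADAR-SUGP1.

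**Figure D1:**
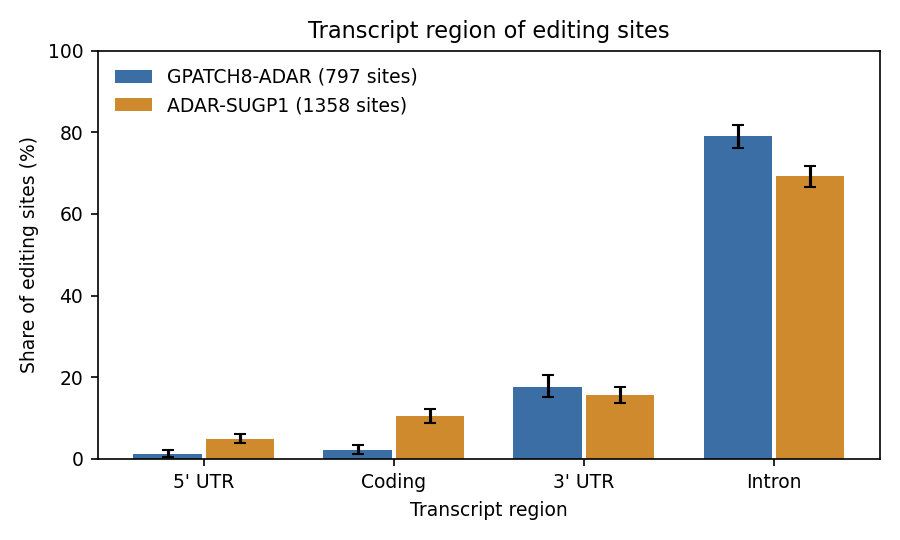
Share of editing sites (vertical axis, percent) in the 5′ UTR, coding sequence, 3′ UTR and introns (horizontal axis) for GPATCH8-ADAR (797 sites, blue) and ADAR-SUGP1 (1358 sites, orange). Error bars are 95% exact binomial intervals over sites; coding sites were 2.13% and 10.4%, and intronic sites 79.0% and 69.2%.

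By Fisher's exact test (two-sided, Benjamini-Hochberg over 6 regions), the share with ADAR-SUGP1 was higher by 8.25 percentage points for coding sites (adjusted p = 1.13e-13), by 3.73 for the 5′ UTR (adjusted p = 1.83e-06) and by 7.63 for transcripts with a stop-codon site (adjusted p = 7.49e-09). The intronic share fell by 9.83 points from GPATCH8-ADAR to ADAR-SUGP1 (same exact test, adjusted p = 1.29e-06). By the same exact test no difference was detected for the 3′ UTR (-2.15 points, adjusted p = 0.246) or the promoter (-0.500 points, adjusted p = 0.358). When whole genes were resampled, so that the sites of a gene stayed together, the coding difference had a 95% interval of 6.12 to 10.4 points and the intronic difference one of -14.6 to -4.98. Among genes with 1 listed transcript, a restriction chosen after seeing the data, the stop-codon difference was 3.31 points (0.768% and 4.07%, Fisher's exact test, adjusted p = 0.000291). A restriction to the 156 transcripts listed for both fusions was chosen after seeing the data. Among them no region passed Fisher's exact test over sites, which leaves out the pairing of transcripts. Coding sites were 0 of 229 and 3 of 206 (1.46 points, Fisher's exact test, adjusted p = 0.632). Intronic sites were 85.2% and 84.5% (-0.687 points, Fisher's exact test, adjusted p = 1). The stop-codon difference among these transcripts was -0.641 points (Fisher's exact test, adjusted p = 1), opposite in sign to that over all transcripts. With transcripts paired, the permutation set first gave p = 0.0234 for coding sites and p = 0.855 for introns. It was replaced, after its result was seen, by an exact sign test. For coding sites 3 transcripts had more with ADAR-SUGP1 and 0 had more with GPATCH8-ADAR (exact sign test, p = 0.25, the lowest possible with 3). For introns these numbers were 32 and 43 (exact sign test, p = 0.248). The paired tests of coding sites thus disagree and do not decide whether a difference remains. Each fusion was sequenced in its own run, so fusion and run cannot be told apart, and the intervals cover counting error or the spread between genes, not between libraries.

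Both fusions edited 162 of the 1513 genes listed for either, which is 28.7% of the GPATCH8-ADAR genes and 14.6% of the ADAR-SUGP1 genes. Ranked by the smaller of the site counts, NDUFV3 came first with 7 sites with GPATCH8-ADAR and 5 with ADAR-SUGP1, followed by the zinc transporter SLC30A5 with 4 and 3 intronic sites. C14orf37 (current symbol ARMH4) had 2 and 3 intronic sites. CCAR1, a regulator of cell cycle and apoptosis, had 4 and 2 intronic sites, EIF3L 6 and 2, and the actin-binding cortactin gene CTTN 4 and 2, 1 of the former in a 5′ UTR. DAZAP1, an RNA-binding protein, DEGS1, a ceramide synthesis enzyme, the DNA repair gene FANCA and the mitotic spindle gene HAUS6 had 2 intronic sites with each fusion.

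Against a background of 20254 genes (RefSeq protein-coding genes and all listed genes), 30.96 shared genes would come from lists of these sizes, so the overlap was 5.23 times larger (Fisher's exact test, one-sided, p = 5.09e-73). Genes that were not expressed could not have been called, and with an assumed 8000 callable genes the overlap was 2.07 times the 78.4 expected (Fisher's exact p = 9.38e-22). Either background treats all its genes as equally likely to be listed, which was not checked. These p-values therefore do not show that the proteins contact the same transcripts. The overlap was 121 genes among those with an intronic site in each list (416 and 709 genes) and 17 among those with a 3′ UTR site (101 and 177 genes). None of the 15 genes with a coding site with GPATCH8-ADAR was among the 128 with a coding site with ADAR-SUGP1, where 0.0948 would come from chance, too few for the overlap to be tested. Of the 155 shared genes with transcript-body sites in both lists, 135 (87.1%) had their largest site count in the same region in both, against 109.9 (70.9%) when the pairing of genes was permuted (permutation test, one-sided, p = 0.0001, the smallest that 10000 permutations can give). Ties went first to the 3′ UTR and last to introns. This comparison was chosen after seeing the data, in place of an overlap of positions, which the tables do not give. It cannot stand for such an overlap, because the permutation ignores which regions a gene's own transcript offers. All exonic sites lay in protein-coding entries, and 149 of the 162 shared genes had at least 1 identical transcript listed for both fusions. Agreement above the permuted value could therefore arise without nearby sites. Introns were the main region in both lists for 119 of these genes and the 3′ UTR for 16. Across the 162 shared genes, the site counts of the fusions were weakly correlated (Pearson's r = 0.207, permutation p = 0.01; Spearman's rho = 0.210, permutation p = 0.007). Without the 2 genes whose GPATCH8-ADAR count lay farthest from its median, r was 0.138. Genes far from the median in the ADAR-SUGP1 count were not left out. Genes are not independent replicates.

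**Figure D2:**
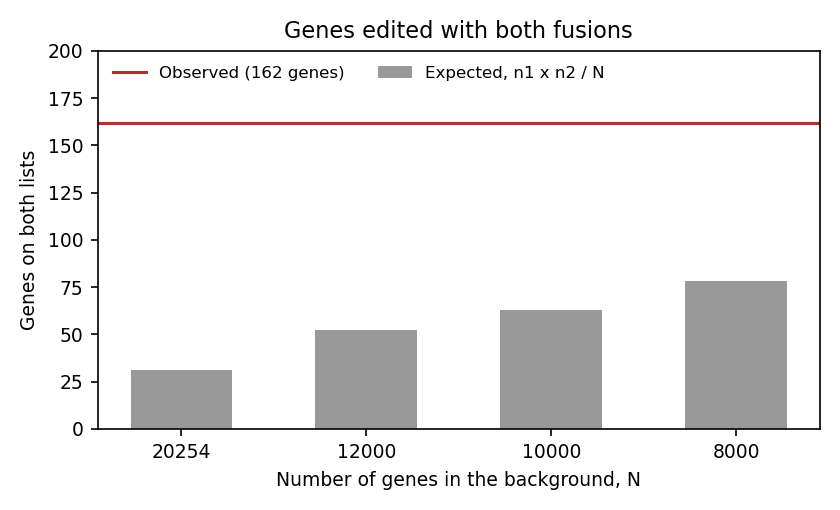
Number of genes on both lists (vertical axis) expected from the list sizes for 4 assumed numbers of genes in the background (grey bars, horizontal axis), with the 162 genes observed (red line). The expected number is 30.96 at 20254 genes and 78.4 at 8000 genes.

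The mean number of sites per gene was higher with GPATCH8-ADAR than with ADAR-SUGP1, while the median was 1 with both (difference 0, permutation p = 1). Most genes held 1 site with either fusion, so the test of medians could not have found a difference. The mean with ADAR-SUGP1 minus that with GPATCH8-ADAR was -0.187 sites per gene (95% interval over genes -0.282 to -0.0948, permutation test, two-sided, p = 5e-05). Genes on both lists entered both sides of this test without pairing. Among genes on 1 list only, a restriction chosen after seeing the data, the difference was -0.183 (95% interval -0.292 to -0.0817, same permutation test, p = 0.00015). At least 2 sites were present in 159 of 565 genes (28.1%) with GPATCH8-ADAR and 214 of 1110 (19.3%) with ADAR-SUGP1. Among the 162 genes edited with both, the means were 1.54 ± 1.10 and 1.51 ± 1.03 (SD, n = 162 genes), a difference of -0.0309 (95% interval -0.241 to 0.173, permutation of signs within genes, p = 0.814). In these genes 42 had more sites with GPATCH8-ADAR, 38 had more with ADAR-SUGP1, and 82 had equal counts.

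Splicing factor transcripts were edited with both fusions. Counts of gene groups cover the members of fixed lists, which do not hold every gene of a pathway or cell type. The genes that could have been called are not known, so no list was tested for enrichment against them. Of the U2 snRNP and branchpoint recognition factors, 6 were edited with GPATCH8-ADAR, among them the U2 snRNP components SF3A2, SF3B3 and PHF5A, the helicase DDX46, U2SURP and RBM39, with 2 intronic sites each except PHF5A, which had 1. ADAR-SUGP1 edited 4, the splicing regulator RBM5 with 4 intronic sites, RBM39 with 2, and SF3B3 and the branchpoint-binding protein SF1 with 1 each. SR proteins and hnRNPs numbered 3 with GPATCH8-ADAR (PTBP2 with 3 intronic sites, HNRNPC with 2, SRSF3 with 1 in its 3′ UTR) and 12 with ADAR-SUGP1 (RALY and SRSF11 with 2 intronic sites each). Other spliceosome proteins numbered 9 with each fusion, 3 of them shared, including SRPK1, the kinase of SR proteins, with 3 and 1 intronic sites. The snRNP core gene SNRPB had 3 intronic sites with ADAR-SUGP1, and the U5 component SNRNP40 had 3 with GPATCH8-ADAR. G-patch protein transcripts numbered 1 (TFIP11) and 4 (RBM5, RBM6, CMTR1 and SON). Of genes whose splicing is known to be altered by SF3B1 mutation, GPATCH8-ADAR edited 2, the amino acid transporter subunit SLC3A2 with 4 intronic sites and ENOSF1 with 1. ADAR-SUGP1 edited 5, ENOSF1 with 4 intronic sites, the calcium channel gene ORAI2 with 2 in its 3′ UTR, and DVL2, PPOX and PPP2R5A with 1 intronic site each. MAP3K7 and BRD9, further targets of this kind, were on neither list.

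Housekeeping groups were also present in both lists. Cytosolic ribosomal proteins numbered 6 with GPATCH8-ADAR and 24 with ADAR-SUGP1, where RPL31 had 7 sites and RPL3, RPL5 and RPL12 had 3 intronic sites each; RPL24 was shared. Translation factors numbered 8 (EIF4B and PABPC1 with 3 intronic sites each) and 13 (EIF3K with 3). Oxidative phosphorylation genes numbered 6 and 12, of which NDUFV3, NDUFS1 and NDUFB1 were shared, and ATP5B, a catalytic subunit of ATP synthase, had 3 intronic sites with ADAR-SUGP1. Zinc finger genes numbered 18 (ZNF789 with 3 sites in its 3′ UTR) and 26 (ZNF346 with 4 intronic sites). Chromatin regulators numbered 6 (DNMT1 with 5 and BRD8 with 4 intronic sites) and 16 (HDAC10 with 4 sites). Ubiquitin ligases and deubiquitinases numbered 10 and 20, cell cycle genes 6 and 12, chaperones 4 and 6, named nuclear and non-coding RNAs 6 and 19, and abundant HEK293T transcripts 4 and 15. Genes known for endogenous A-to-I editing numbered 2 (MDM4 and UBE2O, 1 site each) and 5 (among them UBE2O and NEIL1 with 3 intronic sites each). Histones numbered 1 and 1. The fixed list of interferon and innate immune genes had 0 and 1 edited members (EIF2AK2), and those of mitochondrially encoded genes and of hematopoietic markers had none. Outside these lists, and chosen after their values were seen, the interferon signalling kinase TYK2 had 4 and 2 intronic sites, the leukocyte integrin ITGB2 had 1 site with GPATCH8-ADAR, and HAVCR2, known from immune cells, had 2 with ADAR-SUGP1. The interferon and innate immune genes IFNAR1, IRF3 and IRAK4, also outside the list, had 1 site each with ADAR-SUGP1.

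**Figure D3:**
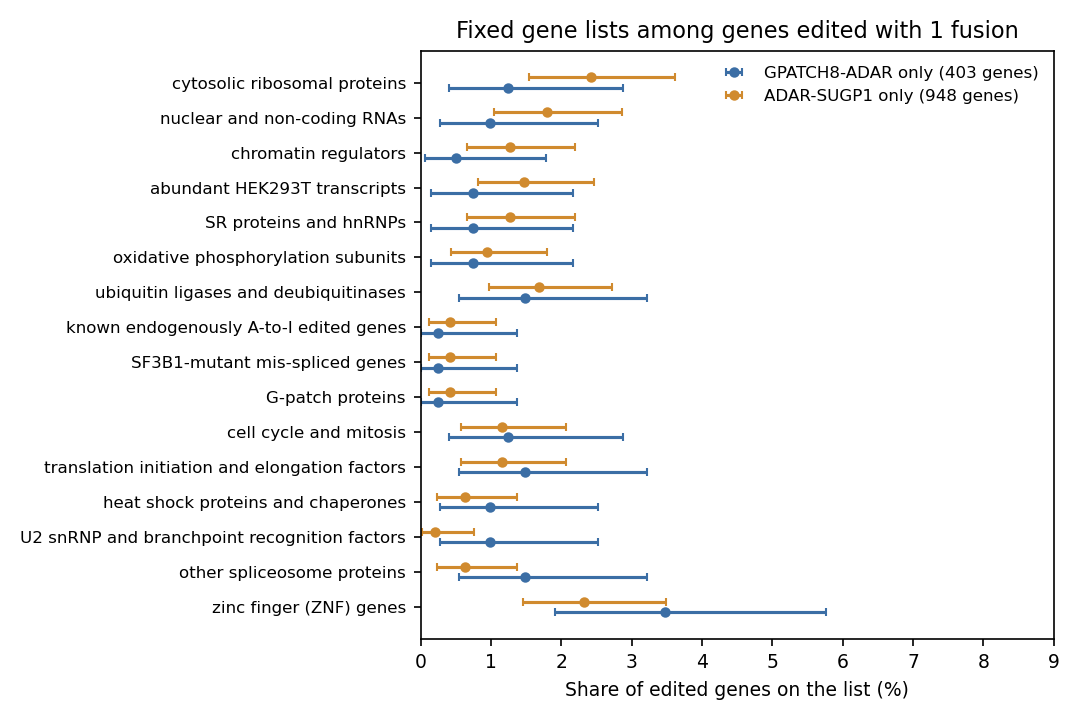
Share of the genes edited with 1 fusion (horizontal axis, percent) that belong to each of 16 gene lists (vertical axis), for 403 genes of GPATCH8-ADAR (blue) and 948 genes of ADAR-SUGP1 (orange). Bars are 95% exact binomial intervals; ribosomal proteins made up 1.24% and 2.43%, and U2 snRNP and branchpoint factors 0.993% and 0.211%.

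Membership in these lists was compared between the 403 genes edited with GPATCH8-ADAR alone and the 948 edited with ADAR-SUGP1 alone. Of 16 lists with at least 3 members, 0 passed an adjusted p of 0.05 and 0 an unadjusted p of 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over 16 lists). The lowest p was that of the U2 snRNP and branchpoint factors, at 0.993% (95% exact interval 0.271 to 2.52) against 0.211% (0.0256 to 0.760) of genes (p = 0.0687, adjusted p = 0.855). Ribosomal proteins stood at 1.24% (0.404 to 2.87) and 2.43% (1.54 to 3.62), with an adjusted p of 0.855 by the same exact test.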

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

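The tests of unspliced RNA and of sequencing run, the limits to genes with 1 listed transcript and to transcripts listed for both fusions, and the sign test were chosen after the regional totals had been seen. Differences between the fusions passed their tests for 5 results. These are not independent, since the 5′ UTR, coding, 3′ UTR and intronic shares of a fusion add up to the whole. The share of sites with ADAR-SUGP1 minus that with GPATCH8-ADAR was 8.25 percentage points for coding sequence, 3.73 for the 5′ UTR and -9.83 for introns, the share of transcripts with a stop-codon site differed by 7.63 points, and the mean number of sites per gene differed by -0.187, with no difference in the median, which was 1 with both fusions, and -0.0309 among genes on both lists (permutation p = 0.814).

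The higher coding share was weighed as 1 pattern. A few genes with many sites are argued against, since with 1 random site per gene the median difference was 8.71 points (median Fisher p = 4.66e-10, largest of 100 draws 1.80e-09), and counting several transcripts of a gene is argued against by a difference of 7.06 points (95% interval 5.01 to 9.21) among genes with 1 listed transcript. A lower share of unspliced RNA in the ADAR-SUGP1 libraries stays open. If it raised coding and 3′ UTR sites alike, it could not be the whole of the pattern. Coding sites were 10.2% and 33.7% of exonic sites, a difference of 23.6 points (interval 16.2 to 30.8). The regional totals, seen before this test was chosen, had already fixed that outcome. Whether unspliced RNA acts alike on coding and 3′ UTR sites was not tested. Different transcripts counted for the fusions stay open: among those listed for both, coding sites were 0 of 229 and 3 of 206, a difference of 1.46 points whose interval (0 to 3.35) lies below 8.25, the outcome set for this explanation, while the permutation set first gave p = 0.0234, the outcome set against it. That permutation was replaced after its result was seen, since unequal site totals break its ties, by an exact sign test that cannot go below p = 0.25 with 3 transcripts. Sequencing run cannot be told apart from fusion, since 0 fusions were sequenced in more than 1 run. Endogenous editing left after the subtractions was not tested for this pattern and stays open, since control values are not among the columns. The only untransfected library was sequenced in the run of ADAR-SUGP1, so whether endogenous editing was removed equally for the fusions is unknown. A difference in where the proteins contact RNA also stays open as untested.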

How the results depend on the processing

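The restrictions to genes with a transcript-body site, to protein-coding entries, to genes on 1 list, to genes with 1 listed transcript and to transcripts listed for both fusions, the overlaps by region and by transcript identifier, the highest transcript of each gene and the permutation over genes were chosen after seeing the data. Of the alternatives for the main results, 53 kept direction and side of the threshold (counts within 1.5 times), 5 lost the call, 2 changed sign and 2 moved. Most of the losses came from transcripts listed for both fusions, where the differences in share were 0.485 percentage points for the 5′ UTR, 1.46 for coding sequence and -0.687 for introns, and that for the stop codon turned to -0.641; among genes with 1 listed transcript the stop-codon difference kept its call at 3.31. The former setting leaves 229 and 206 sites, its calls rest on Fisher's exact test without pairing of transcripts, and the cause was not tested. The overlap ran from 2.07 times expectation (8000 genes) to 19.3 (genes with a 3′ UTR site), except for genes with a coding site, where 0 were shared and 0.0948 expected, too few to test. Requiring 2 sites left 159 genes with GPATCH8-ADAR and 214 with ADAR-SUGP1, by construction. The difference in sites per gene was 0 for medians (permutation p = 1). That outcome was fixed in advance because most genes held 1 site, so this loss of the call carries no weight. Among genes on both lists the difference was -0.0309 (permutation p = 0.814), and the cause was not tested. No gene list passed Fisher's exact test after adjustment under any alternative run (lowest unadjusted p = 0.0443, adjusted p = 0.620, for ribosomal proteins with at least 2 sites per gene); the difference in share, in percentage points, changed sign with at least 2 sites per gene for cell cycle genes (0.312), SR proteins and hnRNPs (-0.429), oxidative phosphorylation (-0.429), zinc finger genes (0.721), translation factors (0.624) and chaperones (0.838), and with shared genes counted in both for cell cycle genes (0.0191). No paired analysis was possible because the columns carry no replicate values, and for the same reason no replicate was left out and no level, coverage or position alternative was run. Low counts, mostly 1 site per gene, limit what can be said of any single gene.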

Other observations

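The groups in this paragraph were chosen after seeing the data. Nucleoporin transcripts numbered 7 with GPATCH8-ADAR, with 18 sites in all, of which NUP205 held 8, NUP153 4 and NUP133 2. With ADAR-SUGP1 they numbered 6, with 1 site each, and NUP85 was shared. DNA replication factors numbered 3 with GPATCH8-ADAR, with 4 sites, and 11 with ADAR-SUGP1, with 23 sites; MCM7 held 5, RFC3 4, and MCM5 and POLD3 3 each. The 3 edited with GPATCH8-ADAR, POLE2, MCM8 and RFC3, were all among the 11. Aminoacyl-tRNA synthetases numbered 4 (IARS with 3 sites) and 7, with IARS and VARS2 shared, proteasome subunits 4 and 3, with PSMD4 and PSMD7 shared, mitochondrial ribosomal proteins 4 and 8, with MRPL19 and MRPL32 shared, and DNA repair genes 3 and 9, with FANCA and PRKDC shared. Of the mitochondrial ribosomal proteins, MRPS18C with GPATCH8-ADAR and MRPL34, MRPL38 and MRPS30 with ADAR-SUGP1 were listed with no counted site. None of these 6 groups differed between genes edited with 1 fusion alone (Fisher's exact test, two-sided, lowest p = 0.0954 for nucleoporins, adjusted p = 0.343).

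The excess of genes on both lists was weighed as a pattern, with the number of callable genes and the overlaps by region examined after the overlap had been seen; it would equal chance if 3871 genes could have been called with equal chance, a number above the 1513 genes listed and below the 20254 of the background, but it would take 2438 for genes with an intronic site, 2507 for genes with an exonic site, 1418 for genes with at least 2 sites and 1052 for genes with a 3′ UTR site. A set of 3871 equally callable genes therefore leaves part of the overlap unaccounted for in each of these subsets, the intronic genes included; each may have a smaller callable set of its own, which the tables do not give, so the explanation stays open. Clustered editing left after the subtractions stays open because its test is void: genes with more sites are likelier to be on both lists whatever the reason, and shared genes had 0.338 more sites per gene than other genes with ADAR-SUGP1 (95% interval 0.175 to 0.509) and 0.186 more with GPATCH8-ADAR (interval -0.00463 to 0.384), or 0.290 and 0.138 among genes with a transcript-body site. Deep reading of abundant transcripts was tested through the abundant, ribosomal and translation lists, which made up 2.47% of shared and 4.52% of other genes (odds ratio 0.536, 95% interval 0.140 to 1.47, Fisher's exact p = 0.304), an interval too wide to decide. Contact of both proteins with the same transcripts stays open as untested, since positions and control values are not among the columns.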
